A study of Danio rerio with 72 samples.

How the data were processed

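The data are read counts per gene of 72 RNA-seq libraries from SR4G zebrafish: 24 from larval heads, 24 from adult hypothalamus and 24 from adult telencephalon. Per the labels, total RNA was column-extracted and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The counts were deposited as whole numbers in a single table with 1 column per library. According to the submitters' processing notes, reads were converted with bcl2fastq 2.17.1.14, trimmed with cutadapt, aligned with STAR 2.5 and analysed with DESeq2. The counting program, its strand setting, the genome build and the annotation release are not given in the sources used here, nor are the versions of cutadapt and DESeq2. Larval titles carry the word whole where adult titles name the brain region, while the tissue label names dissected heads. The titles do not say what is whole, and the tissue label was followed.

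The table holds 31902 entries, of which 31901 are Ensembl gene identifiers and 1 is the reporter transcript d4EGFP. Symbols were joined to 29178 identifiers, and the 2723 without a symbol hold 1.63% of the counts. Symbols follow the reference table, in which many zebrafish genes carry the name of their human ortholog and 6136 entries share a symbol with another identifier. Reads could split between such near-identical copies, so shared names are printed with their identifier. No gene lengths, GC content or coordinates were available, so no value is scaled by length and no bias by length or GC was tested.

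Groups followed the labels: tissue, exposure and stress, 12 groups of 6 libraries. Each tissue was fitted alone as 4 groups in edgeR 4.0.16 under R 4.3.3, with TMM normalization, the default filterByExpr limits (a count of 10, a total of 15) and robust quasi-likelihood F-tests. There were 6 comparisons per tissue and 18 in all. These were fluoxetine against vehicle in unstressed fish, in stressed fish and averaged over both, stressed against unstressed in vehicle and in fluoxetine fish, and their interaction. All p-values printed with a fold are edgeR's quasi-likelihood p, adjusted by Benjamini and Hochberg over the genes tested in that comparison, with a threshold of 0.05. CPM were computed with TMM-scaled library sizes, and log2 CPM with a prior count of 2. A total of 10.2 M counts in the smallest and 22.8 M in the largest library (median 17.7 M) left 20260 genes tested in larval heads, 18380 in the hypothalamus and 18367 in the telencephalon; POMC and SLC6A4 were not tested in the telencephalon because of low counts.

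Gene lists, 34 in number, were written before the data were examined, and 3 were added later; 1356 of their 1439 symbols matched an entry. Lists of at least 5 tested genes were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, and adjusted over the lists and comparisons of a tissue; 234 of 612 list tests passed. With the correlation estimated from the data 4 did, those of the glucocorticoid receptor targets for stress in vehicle larval heads and for stress in fluoxetine fish in each tissue. Every other list result rests on the preset. Counts of members are given over all genes tested and adjusted over the list alone.

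Genes are named by a rule fixed in advance. It takes members of a list past the threshold, up to 20 per comparison, the 5 largest rises and falls with a mean log2 CPM of at least 1, the 3 lowest p where fewer than 5 pass, and up to 4 members of a list that passes. A set of 8 genes of the stress axis, serotonin transport and neuronal activity, and the reporter, are given in every tissue as values; the text prints part of what the rule names. Statements on shared genes come from counts of genes that pass in both comparisons, against the product of their shares as the chance expectation.

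The recovery of edgeR was tested on simulated data, negative binomial counts drawn at each gene's own mean and dispersion with 200 genes changed between unstressed fluoxetine and vehicle libraries. At 2-fold it recovered 62% of changed genes in larval heads, 78% in the hypothalamus and 92% in the telencephalon, and at 1.5-fold 24%, 45% and 60%, with 2, 5 and 8 false calls. The changed genes were taken only from those with a mean log2 CPM above 1, so recovery of genes at lower levels was not simulated. Genes were drawn independently, without the variation that genes share across the real libraries. Recovery and false calls therefore need not hold on the real libraries. Whether replicate numbers pair the libraries of different groups was checked on residual correlations: in each tissue 0 of 6 pairs of groups had every correlation above 0.1, so no block was used. Some pairs of groups came near. Between vehicle and fluoxetine in the unstressed hypothalamus 5 of 6 correlations exceeded 0.1, and 5 libraries matched best with their own number. Libraries were checked for duplicates within groups and none was found, with at least 5.13 times the variance that counting alone gives.

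Each alternative replaced 1 step, although DESeq2 changes size factors, dispersion and test together and voom with quality weights changes both the model and the weights. They were median-of-ratios size factors in edgeR, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, sample quality weights in limma voom, leaving out libraries whose mean correlation with their own group lay more than 3 scaled MADs below the tissue's median, and a fit of only the 2 groups compared. For adults they included the range of library numbers as a term and the sums of replicates n and n+3. Alternatives chosen after the data were seen were leaving out replicates 1 to 3 of the vehicle, unstressed larval group, a covariate for the main axis of variation within groups, and each range of adult library numbers alone. Tissues were set side by side through shared genes and correlations of folds; expression levels were not tested between tissues, the larvae and adults differing also in age and pool size.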

Results

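RNA was sequenced from 72 libraries of SR4G zebrafish, a transgenic line. In it glucocorticoid response elements drive a destabilised green fluorescent protein, whose transcript d4EGFP has its own entry in the count table. The fish had been raised through the first 6 days after fertilization in fluoxetine, a serotonin reuptake inhibitor, at 54 ug/L, or in 0.0053% ethanol as vehicle. Heads were dissected from 6-day-old larvae in pools of 22, and hypothalamus and telencephalon from 6-month-old adults in pools of 5. Each tissue comprised 4 groups, vehicle or fluoxetine and unstressed or stressed, of 6 libraries each. The kind of stressor and the time between stress and sampling are not given in the sources used here. Total counts per library ranged from 10.2 to 19.9 M in larval heads (median 15.8), from 13.2 to 22.8 M in the hypothalamus (median 17.9) and from 14.2 to 21 M in the telencephalon (median 18.5). Levels below are mean ± SD in CPM (counts per M of library), n = 6 libraries per group. Folds come from edgeR with the SE of their log2 value and p-values adjusted over all genes tested in that tissue. The labels describe pools but do not say that the replicates of a group came from separate tanks or clutches. The p-values therefore measure the spread between these pools.

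Features of the libraries accompany several results. In larval heads the 6 vehicle, unstressed libraries differed among themselves, each correlating with the other 5 below the limit set for a library that stands apart; in the hypothalamus vehicle, stressed replicates 1 and 4 did so. Of those larval libraries, replicates 1 to 3 had a mean log2 CPM of 7.37 to 7.52 over the skeletal muscle list and of 6.02 to 6.47 over the liver list, and replicates 4 to 6 had 4.44 to 5.42 and 2.21 to 4.22. The larval vehicle, stressed libraries also divided into replicates 1 to 3 and 4 to 6, with KLF9 at 182.5 to 221.5 and 110.1 to 120.5 CPM and cry3b at 78.38 to 100.1 and 42.44 to 54.19 CPM. Their positions on the main axis of variation within groups were 0.95 to 1.16 and -0.33 to -0.12 SD. Adult libraries carry numbers from 1 to 48, with replicates 1 to 3 of every group among numbers 1 to 24 and replicates 4 to 6 among 25 to 48. Between these ranges 3204 genes differed in the hypothalamus and 3249 in the telencephalon, so each adult count is given with its counts inside either range (n = 3 per group). A lower count there can come from the smaller number of libraries. With the range as a term over all 6 libraries every adult count rose. Fluoxetine in unstressed fish then gave 5220 in the hypothalamus and 2167 in the telencephalon, and stress with vehicle 7423 and 5628.

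**Figure D1:**
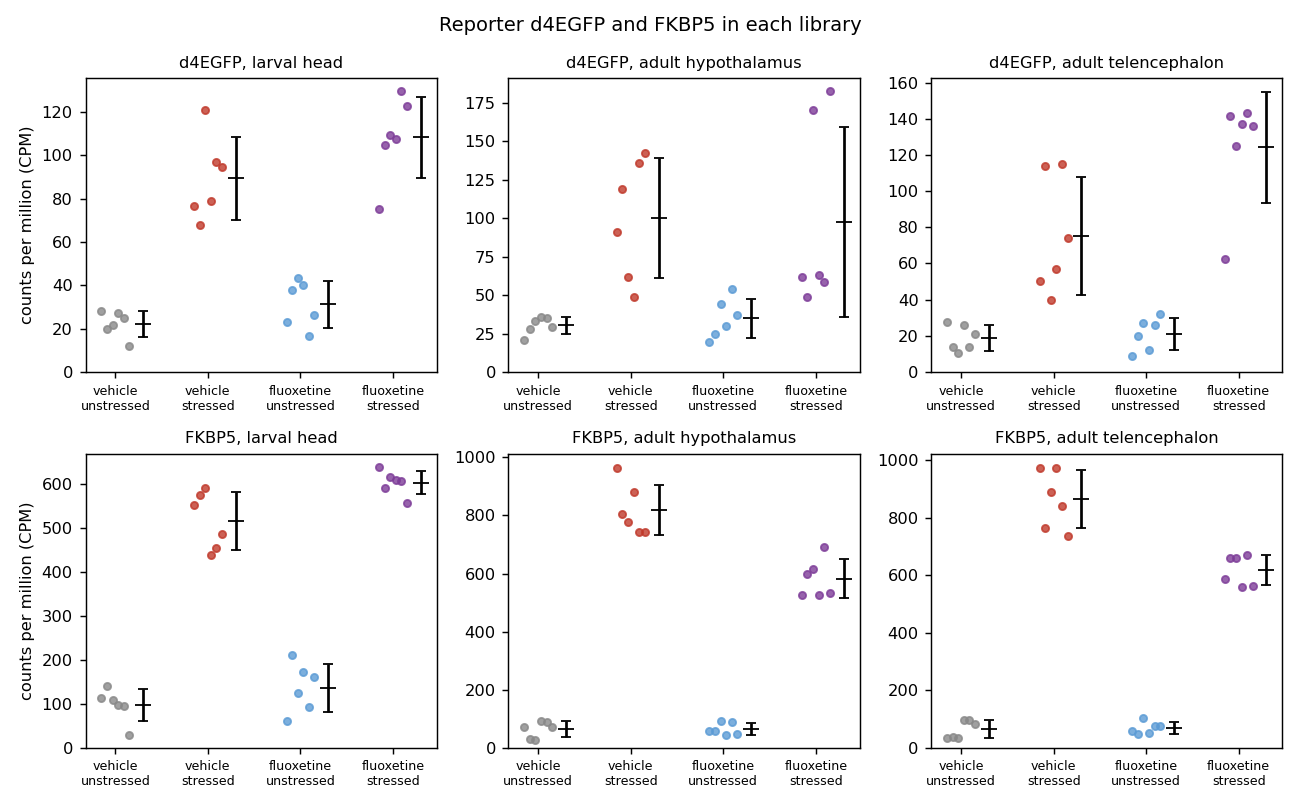
CPM of the reporter transcript d4EGFP and of FKBP5 in each library of the 3 tissues, by group; points are libraries, bars the mean ± SD of 6. In the telencephalon FKBP5 lay between 33.5 and 97.3 CPM in vehicle, unstressed libraries and between 738 and 974 CPM in vehicle, stressed libraries.

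The first question was what stress changed in fish raised without the drug. In vehicle larval heads stress raised the reporter and targets of the glucocorticoid receptor, the nuclear receptor that binds cortisol. The d4EGFP level went from 22.2 ± 5.92 to 89.3 ± 19.1 CPM, 4.02-fold (log2 2.01 ± 0.22 SE, adjusted p = 2.11e-06). FKBP5 (ENSDARG00000028396), a co-chaperone of the receptor, rose from 97.3 ± 37 to 516 ± 64.9 CPM, 5.3-fold (log2 2.41 ± 0.27 SE, adjusted p = 2.86e-06). The kinase gene sgk1 (ENSDARG00000025522) rose 2.78-fold (log2 1.47 ± 0.09 SE, adjusted p = 1.05e-10) and HSD11B2 (ENSDARG00000001975), whose enzyme inactivates cortisol, 2.9-fold (adjusted p = 3.95e-06). Of 33 receptor targets measured, 21 were higher and 1 lower, and 22 and 2 adjusted over the list alone. The list passed the camera test (adjusted p = 6.26e-18; adjusted p = 0.0165 with an estimated correlation).

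Immediate early genes, which encode transcription factors and phosphatases switched on by neuronal activity, rose with stress in the same vehicle larval heads. FOSB (ENSDARG00000055751) rose 28.9-fold from 0.68 ± 0.423 to 20 ± 5.83 CPM (log2 4.86 ± 0.49 SE, adjusted p = 5.55e-07), and fosaa (ENSDARG00000040135) 8.81-fold (adjusted p = 3.34e-07). Others were csrnp1a (ENSDARG00000031426) at 4.82-fold (adjusted p = 3.14e-09), FOS (ENSDARG00000031683) at 17.2-fold and egr1 (ENSDARG00000037421) at 2.66-fold. NPAS4 rose 12.4-fold for ENSDARG00000055752 and 5.23-fold for ENSDARG00000087753, a pair of genes between which similar reads could split. For the former, vehicle, unstressed replicate 6 stood at 65.36 CPM and the other 5 at 9.021 to 14.08. On this list 30 of 39 were higher, 33 adjusted over the list alone, with adjusted p = 0.0857 with an estimated correlation. Hypothalamic neuropeptide genes were higher for 16 of 32 and lower for 1 (19 and 1 adjusted over the list alone; adjusted p = 0.0857 with an estimated correlation). Among them were tac3a (ENSDARG00000093089) at 1.88-fold, NPY (ENSDARG00000036222) at 2.01-fold and adcyap1b (ENSDARG00000027740) at 1.7-fold. CRH (ENSDARG00000027657), the releasing hormone at the head of the stress axis, rose 1.79-fold (log2 0.84 ± 0.17 SE, adjusted p = 0.00208). Circadian clock genes were higher for 22 of 42 (27 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation), with nfil3-6 (ENSDARG00000087188) at 5.68-fold and the clock-linked protease gene USP2 (ENSDARG00000020107) at 2.16-fold. NR3C1 (ENSDARG00000025032), the glucocorticoid receptor itself, had a log2 fold change of 0.21 ± 0.18 SE (adjusted p = 0.421).

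Lower in stressed than in unstressed vehicle larval heads were 45 of 59 skeletal muscle genes (54 adjusted over the list alone), with a median log2 fold change of -1.82. Of 69 nuclear genes of oxidative phosphorylation 44 were lower and 2 higher (57 and 3 adjusted over the list alone), with a median of -0.60. With an estimated correlation these lists had adjusted p = 0.834 and adjusted p = 0.861. HSPA5 (ENSDARG00000103846), a chaperone of the endoplasmic reticulum, fell to 0.399 of its level (log2 -1.33 ± 0.21 SE, adjusted p = 0.000203), POMC (ENSDARG00000043135) to 0.374 (adjusted p = 0.0236), and the calcium-binding muscle gene CASQ1 (ENSDARG00000038716) to 0.064 (adjusted p = 0.00779). The muscle list moved with the spread in the unstressed group: replicates 4 to 6 of vehicle, unstressed lay within the range of the vehicle, stressed libraries (3.25 to 5.93) and replicates 1 to 3 above it. Over oxidative phosphorylation the unstressed libraries ran from 5.45 to 6.90 in mean log2 CPM against 5.54 to 6.04 in the stressed ones. In all, 4303 of 20260 genes passed, 1180 higher and 3123 lower. Without replicates 1 to 3 of vehicle, unstressed 542 genes passed, 362 of them among the 4303, and in a fit of only the 2 groups compared 431 passed. The balance turned in both, to 465 higher and 77 lower and to 296 and 135, and with the axis covariate to 867 and 433. Without those replicates the log2 fold of CASQ1 was 0.29, and CRH, egr1, NPAS4 (ENSDARG00000055752) and POMC no longer passed.

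In the vehicle hypothalamus stress raised the same class of genes. KLF9 (ENSDARG00000068194), a transcription factor gene switched on by the glucocorticoid receptor, went from 5.75 ± 2.88 to 107 ± 24.8 CPM, 18.5-fold (log2 4.21 ± 0.28 SE, adjusted p = 1.01e-10). FKBP5 went from 63.2 ± 27.8 to 819 ± 87.7 CPM, 13-fold (log2 3.7 ± 0.26 SE, adjusted p = 1.72e-10). PDK2 (ENSDARG00000059054) rose 5.11-fold, CEBPD (ENSDARG00000087303) 5.93-fold, and SOCS3 (ENSDARG00000025428, 1 of 2 genes of that name) 7.94-fold. The reporter d4EGFP rose 3.28-fold to 99.8 ± 39 CPM (log2 1.71 ± 0.34 SE, adjusted p = 0.000717). Of 30 receptor targets 20 were higher and 3 lower, the same numbers adjusted over the list alone, with adjusted p = 0.0591 with an estimated correlation. The list of the hypothalamus-pituitary-interrenal axis had 12 of 22 members higher (12 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation). It was led by genes of cortisol breakdown, HSD11B2 at 6.96-fold and hsd20b2 (ENSDARG00000031336) at 2.72-fold. CRH (log2 -0.13 ± 0.17 SE, adjusted p = 0.591), POMC (-0.32, adjusted p = 0.269) and NR3C1 (-0.09, adjusted p = 0.52) did not pass.

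Clock genes moved both ways in the stressed vehicle hypothalamus, 23 of 42 higher and 12 lower (24 and 12 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). The cryptochrome gene cry3b (ENSDARG00000091131) rose 5.01-fold, into a range of 32 to 38.7 CPM, and npas2 (ENSDARG00000016536) 14.8-fold. PER1 (ENSDARG00000056885) fell to 0.403 of its level (log2 -1.31 ± 0.09 SE, adjusted p = 3.32e-10), the other PER1 (ENSDARG00000012499) to 0.46 and BHLHE41 (ENSDARG00000041691) to 0.303; reads could split between the PER1 copies. Cytosolic ribosomal protein transcripts were lower for 71 of 72, also adjusted over the list alone, by a median log2 of -0.59 (RPL10A (ENSDARG00000042905) to 0.665; adjusted p = 0.555 with an estimated correlation). GABA and glutamate genes were higher for 21 of 44 and lower for 1 (22 and 1 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). Endothelial and blood genes were higher for 11 of 26 and lower for 2, also adjusted over the list alone (adjusted p = 0.501 with an estimated correlation). The tight junction gene CLDN5 (ENSDARG00000043716) rose 3.32-fold. Regional hypothalamus markers were lower for 15 of 32 and higher for 4 (17 and 4 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). NKX2-1 (ENSDARG00000019835) fell to 0.439 and ISL1 (ENSDARG00000004023) to 0.432 of their levels. Beside them cerebellum genes, a list added later, had a mean log2 CPM of 3.32 ± 0.59 (2.96 to 4.49) in unstressed and 3.92 ± 0.68 (3.02 to 4.92) in stressed libraries, without passing as a list (adjusted p = 0.686). Of the activity genes, egr1 fell to 0.578 (adjusted p = 7.71e-05) while NPAS4 (ENSDARG00000055752) rose 2.18-fold (adjusted p = 1.04e-06). Skeletal muscle genes were lower for 12 of 45 and higher for 2 (10 and 2 adjusted over the list alone) and as a list did not pass (adjusted p = 0.179), with ckma (ENSDARG00000035327) at 11.1 ± 18.4 CPM in the unstressed and 1.8 ± 1.46 CPM in the stressed libraries. Of 18380 genes 6762 passed, 3722 higher and 3040 lower, against 1645 among numbers 1 to 24 and 3695 among numbers 25 to 48.

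In the vehicle telencephalon KLF9 rose 17.9-fold (log2 4.16 ± 0.28 SE, adjusted p = 8.85e-11), FKBP5 13.6-fold from 63.7 ± 31.5 to 864 ± 101 CPM (log2 3.76 ± 0.26 SE, adjusted p = 1.69e-10), HSD11B2 9.24-fold and IRS2 (ENSDARG00000075282) 2.64-fold. The reporter d4EGFP rose 3.99-fold to 75 ± 32.7 CPM (adjusted p = 0.000131). Receptor targets were higher for 15 of 29 and lower for 4 (16 and 4 adjusted over the list alone; adjusted p = 0.0826 with an estimated correlation). Immediate early genes were higher for 17 of 39 and lower for 2 (17 and 3 adjusted over the list alone; adjusted p = 0.536 with an estimated correlation). These had csrnp1a at 5.4-fold, NPAS4 (ENSDARG00000055752) at 2.83-fold and EGR3 (ENSDARG00000089156) at 2.41-fold but egr1 at 0.597. Genes that mark telencephalic territory were lower for 21 of 27 and higher for 2 (21 and 3 adjusted over the list alone), by a median log2 of -0.55 (adjusted p = 0.0652 with an estimated correlation). These included TBR1 (ENSDARG00000004712), of pallial glutamatergic neurons, at 0.524 (log2 -0.93 ± 0.08 SE, adjusted p = 8.12e-09) and PRDM12 (ENSDARG00000007430) at 0.437. Clock genes were higher for 22 of 42 and lower for 10 (24 and 11 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), with NR1D1 (ENSDARG00000033160) at 0.335 and nfil3-6 at 5.12-fold. Of 18367 genes 4928 passed, 2753 higher and 2175 lower, against 1565 among numbers 1 to 24 and 2325 among numbers 25 to 48.

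**Figure D2:**
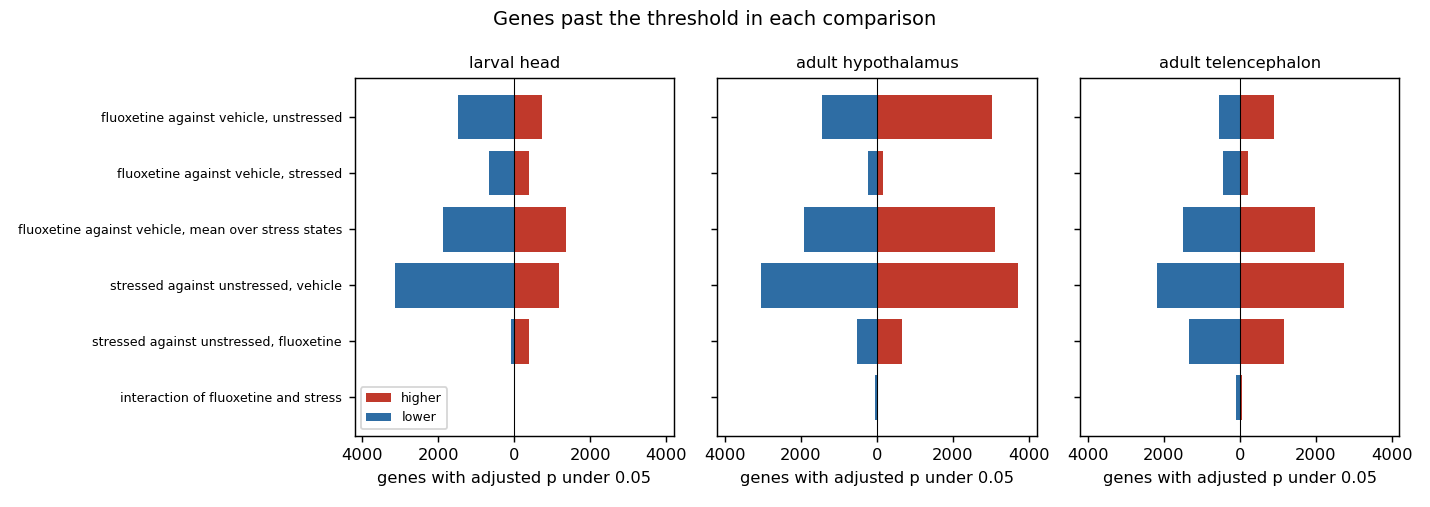
Number of genes past an adjusted p of 0.05 in edgeR for each comparison and tissue, higher counts to the right and lower counts to the left of 0; each bar is 1 comparison. The largest total, 6762 genes, is that of stress in the vehicle hypothalamus, and the interactions gave 27, 94 and 147 genes.

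The second question was how fish raised in fluoxetine responded to stress. In their larval heads d4EGFP rose 3.46-fold, from 31.3 ± 10.8 to 108 ± 18.8 CPM (log2 1.79 ± 0.22 SE, adjusted p = 1.29e-05). There FKBP5 rose 4.42-fold (log2 2.14 ± 0.27 SE, adjusted p = 1.86e-05) and sgk1 2-fold (adjusted p = 5.19e-08). Receptor targets were higher for 11 of 33 (14 adjusted over the list alone), with adjusted p = 0.0165 with an estimated correlation. The clock gene PER2 (ENSDARG00000034503) rose 9.82-fold, from 33.4 ± 10.4 to 328 ± 7.93 CPM (log2 3.3 ± 0.24 SE, adjusted p = 9.22e-09), and cry5 (ENSDARG00000019498) 4.84-fold. Clock genes were higher for 15 of 42 (19 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). Immediate early genes were higher for 15 of 39 (24 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation), with FOSL1 (ENSDARG00000015355) at 22.3-fold. FOS passed at 5.3-fold (adjusted p = 0.0252), but 232.3 CPM in replicate 2 stood against 19.13 to 44.27 CPM in the other 5 stressed libraries. Of 20260 genes 473 passed, 384 higher and 89 lower, and 1322 passed when replicates 1 to 3 of vehicle, unstressed were left out of the fit.

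In the hypothalamus of fluoxetine fish stress raised FKBP5 9.04-fold to 582 ± 66.9 CPM (log2 3.18 ± 0.25 SE, adjusted p = 6.08e-09). It raised KLF9 9.47-fold (log2 3.24 ± 0.27 SE, adjusted p = 1.19e-08), SOCS3 (ENSDARG00000025428) 11.2-fold and PDK2 6.44-fold. The reporter d4EGFP rose 2.8-fold to 97.4 ± 61.4 CPM (adjusted p = 0.00939) and POMC, the precursor of corticotropin, 1.74-fold (adjusted p = 0.033). Receptor targets were higher for 13 of 30 and lower for 1 (17 and 1 adjusted over the list alone), with adjusted p = 0.00163 with an estimated correlation. Serotonin system genes were higher for 5 of 30 (8 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation). TPH1 (ENSDARG00000036082), 1 of 2 genes of that name for the enzyme that starts serotonin synthesis, rose 1.92-fold (log2 0.94 ± 0.13 SE, adjusted p = 2.48e-05) and the receptor gene HTR5A (ENSDARG00000068557) 1.78-fold. Of 18380 genes 1192 passed, 661 higher and 531 lower, against 349 among numbers 1 to 24 and 88 among numbers 25 to 48.

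In the telencephalon of fluoxetine fish FKBP5 rose 9.07-fold to 617 ± 52 CPM (log2 3.18 ± 0.26 SE, adjusted p = 4.31e-09), KLF9 10.7-fold (log2 3.41 ± 0.27 SE, adjusted p = 3.11e-09) and d4EGFP 5.9-fold to 124 ± 30.8 CPM (log2 2.56 ± 0.33 SE, adjusted p = 1.42e-05). Receptor targets were higher for 16 of 29 and lower for 2 (16 and 3 adjusted over the list alone), with adjusted p = 0.00292 with an estimated correlation. Immediate early genes were higher for 19 of 39 and lower for 1 (21 and 3 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), with NPAS4 (ENSDARG00000055752) at 2.93-fold and EGR3 at 2.21-fold. Neuropeptide genes were higher for 10 of 26 and lower for 1 (11 and 2 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). NTS (ENSDARG00000057887), for neurotensin, rose 3.02-fold and the enkephalin gene penka (ENSDARG00000004869) 1.64-fold. Serotonin receptor genes HTR5A, 2.2-fold, htr7a (ENSDARG00000056949), 1.75-fold, and HTR2A (ENSDARG00000057029), 1.59-fold, were among 6 of 27 serotonin system genes that were higher (6 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation). Photoreceptor genes varied between libraries, with opn1sw2 (ENSDARG00000017274) at 37.1 ± 23.4 CPM in unstressed and 2.19 ± 2.52 CPM in stressed libraries. Of 18367 genes 2499 passed, 1166 higher and 1333 lower, a balance that median-of-ratios size factors turned to 1297 and 1149 and DESeq2 to 1646 and 1461, against 609 among numbers 1 to 24 (423 and 186) and 674 among numbers 25 to 48 (450 and 224).

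The next question was what the early exposure changed in fish that were not stressed, in larvae at the end of the exposure and in adults 6 months old. Each of these comparisons has the same vehicle, unstressed libraries as reference as that of stress in vehicle fish. A change found in both was therefore not seen independently. In larval heads ern1 (ENSDARG00000013997), which encodes a sensor of unfolded proteins in the endoplasmic reticulum, rose from 20.6 ± 3.42 to 51.1 ± 13.6 CPM, 2.49-fold (log2 1.31 ± 0.14 SE, adjusted p = 2.1e-05). PLCD3 (ENSDARG00000052957), a phospholipase gene, rose 2.93-fold (log2 1.55 ± 0.17 SE, adjusted p = 2.1e-05). The neuropeptide gene npvf (ENSDARG00000036227) rose 2.14-fold from 4.09 ± 0.912 to 8.73 ± 1.07 CPM (adjusted p = 0.000681), and cyp2ad3 (ENSDARG00000022650), of the cytochrome P450 family that handles drugs, 1.62-fold (adjusted p = 0.000551). The green cone opsin gene opn1mw2 (ENSDARG00000044280) rose 4.95-fold from 34.6 ± 23.5 to 171 ± 55.2 CPM (log2 2.31 ± 0.34 SE, adjusted p = 0.000485). Neuropeptide genes were higher for 8 of 32 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.153 with an estimated correlation), with tac3a at 1.56-fold and kiss1 (ENSDARG00000075829) at 2.37-fold.

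Lower in unstressed fluoxetine larval heads were 11 of 29 genes of cholesterol synthesis (19 adjusted over the list alone; median log2 -0.72; adjusted p = 0.5 with an estimated correlation). HMGCS1 (ENSDARG00000103025) fell to 0.454 (log2 -1.14 ± 0.25 SE, adjusted p = 0.0118), CYP51A1 (ENSDARG00000042641) to 0.286 and DHCR7 (ENSDARG00000103226) to 0.603. Of 34 genes of the unfolded protein response 16 were lower and 2 higher (21 and 2 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), with HSPA5 at 0.478 (log2 -1.07 ± 0.21 SE, adjusted p = 0.00636). Cell cycle genes were lower for 13 of 40 and higher for 1 (35 and 1 adjusted over the list alone; adjusted p = 0.942 with an estimated correlation). Skeletal muscle genes were lower for 8 of 59 (15 lower and 1 higher adjusted over the list alone; adjusted p = 0.962 with an estimated correlation). The cholesterol, unfolded protein response and cell cycle lists follow the spread in the vehicle group. Over cholesterol synthesis its libraries ran from 2.59 to 3.83 in mean log2 CPM against 2.48 to 2.81 with fluoxetine. Over the unfolded protein response they ran from 4.66 to 5.48 against 4.57 to 4.70, and over the cell cycle from 1.18 to 5.16 against 2.5 to 3. The serotonin transporter gene SLC6A4 (ENSDARG00000061165), the target of fluoxetine, had a log2 fold change of -0.45 ± 0.19 SE (adjusted p = 0.107), d4EGFP 0.49 ± 0.22 SE (adjusted p = 0.126) and FKBP5 0.49 (adjusted p = 0.205). In all, 2191 genes passed, 720 higher and 1471 lower. Without replicates 1 to 3 of vehicle, unstressed 758 passed, 221 of them among the 2191, and 35 passed in a fit of only the 2 groups compared. The balance turned here too, to 403 higher and 355 lower and to 26 and 9, and with the axis covariate to 1060 and 593. The genes ern1, PLCD3, npvf and cyp2ad3 passed in both, while HSPA5 did not pass without those replicates.

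**Figure D3:**
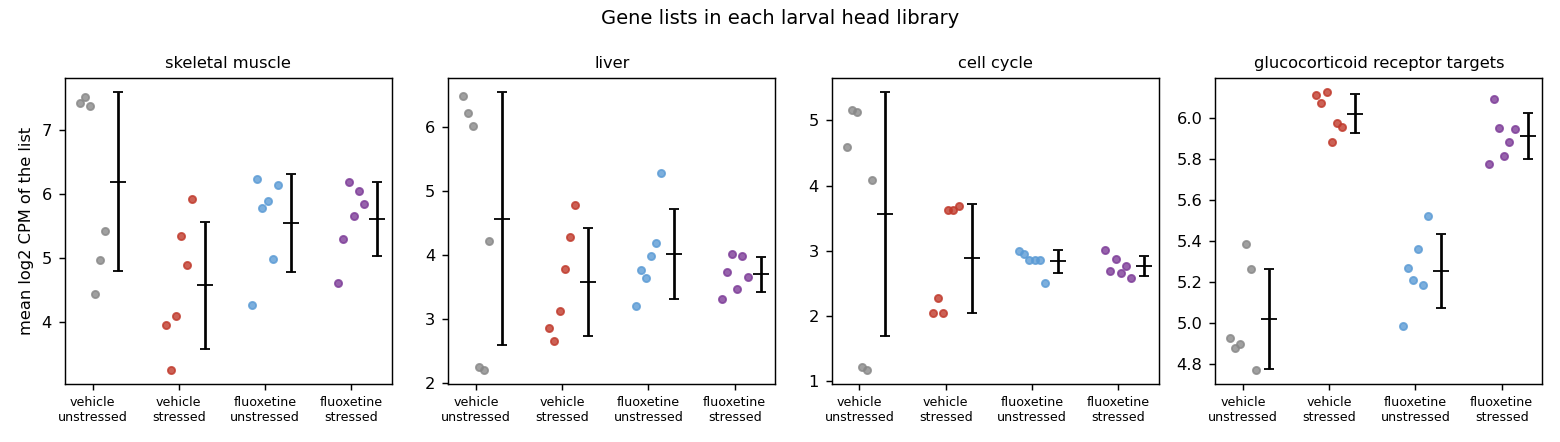
Mean log2 CPM of the skeletal muscle, liver, cell cycle and glucocorticoid receptor target lists in each larval library, by group; each point is 1 library. Over the muscle list the vehicle, unstressed libraries lay between 4.44 and 7.52, and the fluoxetine, stressed libraries had 5.6 ± 0.58 (mean ± SD).

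In the unstressed hypothalamus of adults, 6 months after fertilization, single genes of glia and vessels were higher with fluoxetine. Of 35 radial glia genes 7 were higher and 2 lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.26). PTN (ENSDARG00000102340), a growth factor gene listed for radial glia, rose 1.93-fold from 66.8 ± 10.5 to 129 ± 11.1 CPM (log2 0.95 ± 0.11 SE, adjusted p = 9.25e-05). The astroglial transporter genes SLC6A11 (ENSDARG00000087981) and SLC1A3 (ENSDARG00000043148) rose 3.21-fold (adjusted p = 0.00153) and 3.65-fold (adjusted p = 0.0021), and the carbonic anhydrase gene ca4a (ENSDARG00000043589) 4.73-fold (log2 2.24 ± 0.21 SE, adjusted p = 2.77e-06). Endothelial and blood genes were higher for 8 of 26 and lower for 1, also adjusted over the list alone (adjusted p = 0.511 with an estimated correlation), with the glucose transporter SLC2A1 (ENSDARG00000007412, 1 of 2 genes of that name) at 5-fold and CLDN5 (ENSDARG00000043716) at 2.47-fold. GABA and glutamate genes were higher for 18 of 44 (22 higher and 3 lower adjusted over the list alone; adjusted p = 0.611 with an estimated correlation), including the GABA receptor subunit GABRD (ENSDARG00000059763) at 2.07-fold.

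Lower with fluoxetine in the unstressed hypothalamus were 53 of 72 cytosolic ribosomal protein transcripts (71 adjusted over the list alone), by a median log2 of -0.43 (adjusted p = 0.555 with an estimated correlation); RPL10A stood at 0.744 of its vehicle level (log2 -0.43 ± 0.12 SE, adjusted p = 0.0102). Of 13 mitochondrially encoded transcripts 10 were lower, also adjusted over the list alone, with MT-CYB (ENSDARG00000063924) at 0.676. Of 69 nuclear genes of oxidative phosphorylation 25 were lower (33 adjusted over the list alone), with ATP5MC3 (ENSDARG00000017775) at 0.699. Both lists had adjusted p = 0.555 with an estimated correlation. Neuropeptide genes were lower for 10 of 32, also adjusted over the list alone (adjusted p = 0.555 with an estimated correlation), including TRH (ENSDARG00000006868) at 0.613 (log2 -0.71 ± 0.16 SE, adjusted p = 0.00398) and GAL (ENSDARG00000091377) at 0.627. Hypothalamus markers were lower for 16 of 32 and higher for 1 (16 and 2 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). The mean log2 CPM of cerebellum genes, markers of another brain region, was 3.32 ± 0.59 in vehicle and 3.94 ± 1.21 (2.89 to 5.61) in fluoxetine libraries, a list that did not pass (adjusted p = 0.686). TPH1 (ENSDARG00000036082) fell to 0.636 (log2 -0.65 ± 0.13 SE, adjusted p = 0.00233), CRH to 0.72 (adjusted p = 0.0472) and POMC to 0.652 (adjusted p = 0.0489). FKBP5 (log2 0.03, adjusted p = 0.95) and d4EGFP (0.19, adjusted p = 0.7) did not pass. In all 4478 genes passed, 3027 higher and 1451 lower, against 2292 among numbers 1 to 24 and 1 among numbers 25 to 48, where 3320 had an unadjusted p under 0.05 and DESeq2 passed 574. With each library's position on the main axis of variation within groups as a covariate 1185 passed. No ribosomal protein transcript then passed as lower, and the median log2 of that list was -0.33.

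In the unstressed telencephalon single genes of glia and vessels were higher with fluoxetine. Radial glia genes were higher for 6 of 33 and lower for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.612 with an estimated correlation). SLC2A1 (ENSDARG00000001437) rose 4.49-fold (adjusted p = 0.00411), SLC6A11 3.26-fold (adjusted p = 0.00601) and CLDN5 (ENSDARG00000043716) 2.99-fold (adjusted p = 0.00804). PTN rose 1.65-fold (log2 0.72 ± 0.13 SE, adjusted p = 0.00694) and csf1ra (ENSDARG00000102986), for the receptor that maintains microglia, 3.31-fold (adjusted p = 0.00694). Microglia and macrophage genes were higher for 4 of 32 (7 adjusted over the list alone; adjusted p = 0.536 with an estimated correlation). Endothelial and blood genes were higher for 7 of 27 (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.473 with an estimated correlation). Mitochondrially encoded transcripts were lower for 7 of 13 (10 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), with MT-CO3 (ENSDARG00000063912) at 0.637 (log2 -0.65 ± 0.15 SE, adjusted p = 0.0173). Nuclear genes of oxidative phosphorylation were lower for 11 of 68 (42 adjusted over the list alone; adjusted p = 0.477 with an estimated correlation). The 72 ribosomal protein transcripts had a median log2 fold change of -0.31 (adjusted p = 0.627 with an estimated correlation), with rps20 (ENSDARG00000036044) at -0.38 (adjusted p = 0.0833). In all 1435 genes passed, 897 higher and 538 lower. Inside numbers 25 to 48 edgeR passed 5 genes, and inside numbers 1 to 24 it passed 0, where 2843 had an unadjusted p under 0.05 and DESeq2 passed 120; 20 passed when replicates n and n+3 were summed.

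Between stressed fish of both exposures clock genes differed both ways in the adult tissues, without passing as a list. In the hypothalamus 14 of 42 were higher and 13 lower (14 and 17 adjusted over the list alone; list adjusted p = 0.493). In the hypothalamus cry3b stood at 5.24 ± 0.771 CPM in fluoxetine fish, 0.149 of the vehicle level (log2 -2.74 ± 0.14 SE, adjusted p = 5.76e-13). BMAL1 (ENSDARG00000006791, 1 of 2 genes of that name), an activator at the core of the clock, stood at 0.344 (adjusted p = 1.13e-08). The repressor genes NR1D1 and PER1 (ENSDARG00000056885) were 3.41-fold (adjusted p = 1.13e-08) and 3.11-fold higher (adjusted p = 1.66e-11), and ciarta (ENSDARG00000058094) 2.69-fold (adjusted p = 7.82e-10). FOS was 2.15-fold higher (log2 1.1 ± 0.18 SE, adjusted p = 0.000616) and the chaperone gene HSPD1 (ENSDARG00000056160) stood at 0.713 (adjusted p = 1.78e-05). Its heat shock list had 4 of 33 members lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). FKBP5 had a log2 fold change of -0.49 ± 0.23 SE (adjusted p = 0.294), with its 6 fluoxetine libraries (525 to 692 CPM) all below its 6 vehicle ones (742 to 964), and d4EGFP -0.03 (adjusted p = 0.971). Of 18380 genes 380 passed, 148 higher and 232 lower, against 180 among numbers 1 to 24 and 32 among numbers 25 to 48 (17 and 15); with the axis covariate they were 348 and 339.

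**Figure D4:**
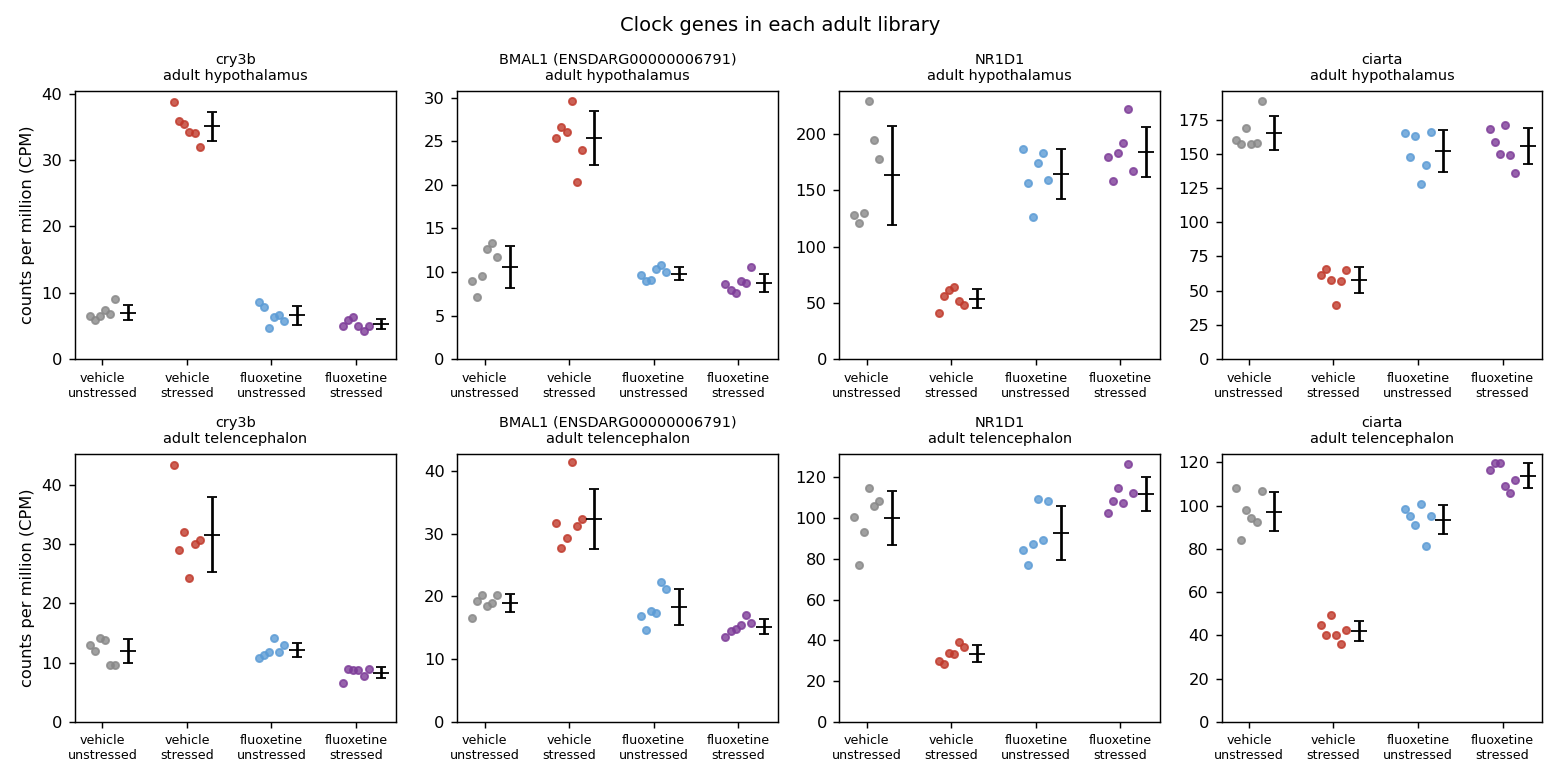
CPM of cry3b, BMAL1 (ENSDARG00000006791), NR1D1 and ciarta in each adult library by group; points are libraries, bars the mean ± SD of 6. For cry3b in the hypothalamus the vehicle, stressed libraries lie between 32 and 38.7 CPM, while no library of the other 3 groups exceeds 9.06 CPM.

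In the stressed telencephalon 12 of 42 clock genes were higher and 13 lower (15 and 16 adjusted over the list alone; list adjusted p = 0.866), with cry3b at 0.262 (log2 -1.93 ± 0.13 SE, adjusted p = 1.33e-10), and BMAL1 (ENSDARG00000006791) at 0.47 (adjusted p = 8.79e-08). NR1D1 was 3.34-fold (adjusted p = 1.97e-11) and ciarta 2.71-fold higher (adjusted p = 3.07e-12) with fluoxetine. Heat shock genes were lower for 8 of 32 and higher for 1 (9 and 1 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). The mitochondrial chaperonin gene HSPE1 (ENSDARG00000056167) stood at 0.623 (log2 -0.68 ± 0.08 SE, adjusted p = 7.14e-06) and HSPA8 (ENSDARG00000037403) at 0.664. Telencephalon markers were higher for 4 of 27 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.155 with an estimated correlation), among them PRDM12 at 1.43-fold. FOS was 1.85-fold higher (adjusted p = 0.000241) and egr1 1.4-fold higher (adjusted p = 0.000746). On their list immediate early genes were higher for 7 of 39 and lower for 2 (10 and 3 adjusted over the list alone; adjusted p = 0.599 with an estimated correlation). FKBP5 (log2 -0.49 ± 0.24 SE, adjusted p = 0.242) and d4EGFP (0.73 ± 0.31 SE, adjusted p = 0.19) did not pass; for FKBP5 the fluoxetine libraries (560 to 670 CPM) again all lay below the vehicle ones (738 to 974). The cone opsin gene opn1lw2 (ENSDARG00000044861) stood at 42.7 ± 62.6 CPM in vehicle and 0.757 ± 0.759 CPM in fluoxetine libraries. Of 18367 genes 645 passed, 213 higher and 432 lower, against 175 among numbers 1 to 24 and 49 among numbers 25 to 48.

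In stressed larval heads ern1 was again higher with fluoxetine, 2.36-fold (log2 1.24 ± 0.14 SE, adjusted p = 5.5e-05), as was npvf, 2.08-fold (adjusted p = 0.00137). So were KYAT3 (ENSDARG00000102423), which encodes an enzyme of kynurenine metabolism, 3.57-fold, and hsd20b2, 1.85-fold (adjusted p = 0.00262). Clock genes HLF (ENSDARG00000061011) at 0.479 (log2 -1.06 ± 0.16 SE, adjusted p = 0.000849), nfil3-5 (ENSDARG00000094965) at 0.391 and CLOCK (ENSDARG00000011703) at 0.487 were lower and cry5 1.95-fold higher. Immediate early genes were lower for 7 of 39 and higher for 1 (12 and 1 adjusted over the list alone; adjusted p = 0.716 with an estimated correlation). These included fosaa at 0.37 (log2 -1.43 ± 0.28 SE, adjusted p = 0.00661), BTG2 (ENSDARG00000020298) at 0.469 and DUSP1 (ENSDARG00000100515) at 0.56. Skeletal muscle genes had a median log2 fold change of 0.93 (adjusted p = 0.861 with an estimated correlation). Of 20260 genes 1052 passed, 380 higher and 672 lower. In a fit of only the 2 groups compared 2928 passed, and 2764 passed without replicates 1 to 3 of vehicle, unstressed.

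Averaged over both stress states, ern1 was 2.42-fold higher with fluoxetine in larval heads (log2 1.28 ± 0.1 SE, adjusted p = 3.68e-08) and npvf 2.1-fold (adjusted p = 5.43e-06). Higher there, too, was opn1mw2, 3.54-fold (adjusted p = 3.45e-05). Neuropeptide genes were higher for 12 of 32 and lower for 1 (13 and 2 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation). Lysosomal genes were lower for 10 of 43 (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.201 with an estimated correlation), such as ARSA (ENSDARG00000042270) at 0.687 and grnb (ENSDARG00000025081) at 0.773. Here 3238 genes passed, 1373 higher and 1865 lower. The axis covariate turned the balance to 2833 and 2525, and without replicates 1 to 3 of vehicle, unstressed 4398 passed, 2029 of them among the 3238. In the hypothalamus KCNJ13 (ENSDARG00000043443), a potassium channel gene listed for choroid plexus, was 3.42-fold higher (log2 1.77 ± 0.26 SE, adjusted p = 0.00012) and PTN 1.5-fold (adjusted p = 5.96e-05). Its ribosomal protein transcripts were lower for 35 of 72 (58 adjusted over the list alone; median log2 -0.28; adjusted p = 0.569 with an estimated correlation). There 5022 genes passed, 3107 higher and 1915 lower, against 3512 among numbers 1 to 24 and 20 among numbers 25 to 48. In the telencephalon KCNJ13 was 2.37-fold higher (adjusted p = 0.000555), and mitochondrially encoded transcripts were lower for 11 of 13, also adjusted over the list alone (adjusted p = 0.442 with an estimated correlation). Heat shock genes were lower for 10 of 32 and higher for 1 (11 and 3 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), such as FKBP4 (ENSDARG00000008447) at 0.81. In that tissue 3489 passed, 1985 higher and 1504 lower, against 131 among numbers 1 to 24 (47 and 84) and 156 among numbers 25 to 48 (106 and 50). Sums of replicates n and n+3 gave 442 higher and 464 lower.

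The interaction asked whether the response to stress itself differed between exposures. Clock genes passed in both adult tissues. In the hypothalamus 9 of 42 clock genes had a higher and 13 a lower response with fluoxetine (10 and 22 adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). The response of cry3b differed by a log2 of -2.67 ± 0.19 SE (adjusted p = 1.35e-09) and that of NR1D1 by 1.76 ± 0.2 SE (adjusted p = 1.12e-05). That of ciarta differed by 1.55 (adjusted p = 2.01e-07) and that of BMAL1 (ENSDARG00000006791) by -1.43 (adjusted p = 2.97e-05). FOS differed by 1.26 (adjusted p = 0.0142), abcg2a (ENSDARG00000100075), a drug efflux pump gene, by -1.87 (adjusted p = 0.000477), and NR1I2 (ENSDARG00000029766), a nuclear receptor that senses foreign compounds, by -1.19 (adjusted p = 0.000477). FKBP5 (-0.52 ± 0.33 SE, adjusted p = 0.458) and d4EGFP (-0.23 ± 0.47 SE, adjusted p = 0.85) did not pass. Of 18380 genes 94 passed, 33 higher and 61 lower, against 35 among numbers 1 to 24 and 7 among numbers 25 to 48 (6 and 1). Without vehicle, stressed replicates 1 and 4, the hypothalamic libraries that stand apart, 384 passed.

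In the telencephalon the interaction of ciarta was a log2 of 1.49 ± 0.11 SE (adjusted p = 2.48e-09), and of NR1D1 1.85 ± 0.14 SE (adjusted p = 8.62e-09). For cry3b it was -1.95 ± 0.18 SE (adjusted p = 2.12e-07), and smu1b (ENSDARG00000051970), a splicing factor gene, had 1.69 ± 0.09 SE (adjusted p = 1.12e-11). FOS (0.94, adjusted p = 0.0129) and egr1 (0.65, adjusted p = 0.0022) passed, as did HSPA8 (-0.52, adjusted p = 0.018). Of 42 clock genes 9 had a higher and 12 a lower response (11 and 19 adjusted over the list alone), moving both ways in a list that did not pass (adjusted p = 0.162). The heat shock list had 3 of 32 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation). FKBP5 (-0.58 ± 0.34 SE, adjusted p = 0.494) and d4EGFP (0.57 ± 0.45 SE, adjusted p = 0.65) did not pass. Of 18367 genes 147 passed, 45 higher and 102 lower, against 36 among numbers 1 to 24 and 18 among numbers 25 to 48 (10 and 8).

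In larval heads the response of PER2 to stress was larger with fluoxetine by a log2 of 1.73 ± 0.32 SE (adjusted p = 0.0296). That of cry5 was larger by 1.26 (adjusted p = 0.0446). HSPA5 had an interaction of 1.55 (adjusted p = 0.0301), its level falling from 167 ± 72.7 to 66.6 ± 5.15 CPM with stress in vehicle fish and standing at 79.8 ± 15 and 93.2 ± 13.9 CPM with fluoxetine. The response of ets2 (ENSDARG00000103980) was smaller by a log2 of -1.25 (adjusted p = 0.039). Immediate early genes had a median of -0.73 (adjusted p = 0.356 with an estimated correlation), and fosaa, at -1.77, did not pass (adjusted p = 0.0885). FKBP5 (-0.26, adjusted p = 0.741), d4EGFP (-0.22 ± 0.3 SE, adjusted p = 0.743) and egr1 (-1.20, adjusted p = 0.19) did not pass. Of 20260 genes 27 passed, 23 higher and 4 lower. With the replicate number as a block 1 passed, 0 higher and 1 lower, so that PER2, cry5 and HSPA5 no longer passed. Without replicates 1 to 3 of vehicle, unstressed the balance turned to 9 higher and 25 lower, with 9 genes shared with the 27, and with the axis covariate it was 57 and 61. HSPA5 and ets2 no longer passed without replicates 1 to 3 of vehicle, unstressed.

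Genes shared between comparisons that have no library in common describe how alike the responses were. Across genes, which are not independent replicates, the stress responses of vehicle and fluoxetine fish correlated with Pearson's r of 0.5 in larval heads, 0.52 in the hypothalamus and 0.37 in the telencephalon. In the telencephalon 846 genes were higher in both and 672 lower in both, against 174.8 and 157.9 by chance, with 15 opposite. The fluoxetine effects of unstressed and stressed fish correlated with r of 0.3, 0.4 and 0.1. For the telencephalon Spearman's correlation was 0.37, and Pearson's 0.26 over genes with a mean log2 CPM of at least 1. In larval heads 115 genes were higher in both against 13.5 by chance and 100 lower in both against 48.8. Between tissues, the fluoxetine effect averaged over stress states shared 1438 higher and 760 lower genes between hypothalamus and telencephalon against 335.4 and 158.3 by chance, with 3 opposite (r 0.67). That expectation takes the libraries as independent, whereas those of the same group and number in both tissues had residuals correlated at a mean of 0.27, and whether they share pools is not given in the sources used here. Between larval heads and the hypothalamus 34 were higher in both, 39 lower in both and 1177 opposite (r -0.31), against 217 and 170 shared by chance. Each effect correlated with the main axis of variation within groups of its own tissue, at r 0.512 in larval heads and -0.536 in the hypothalamus. The sign of an axis is arbitrary and the axes of the tissues were not matched. The opposite signs therefore say nothing on the opposite genes. In all 6 stress comparisons 98 genes passed, 97 higher in each and 1, simc1, lower in each. The largest mean log2 fold changes over the 6 were those of KLF9 at 3.10, FKBP5 at 3.06, FOSB at 2.85, SOCS3 (ENSDARG00000025428) at 2.54 and HSD11B2 at 2.26.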

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

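The test of time of day on the clock genes was chosen only after the result was seen. For the ranges of library numbers the prediction was written before its test, which uses fits of each range alone. Those fits were chosen after the data were seen. The stress effect differed between fluoxetine and vehicle by an interaction test in 27 genes of larval heads, 94 of the hypothalamus and 147 of the telencephalon. In both adult tissues the clock genes among them set the vehicle, stressed libraries apart from the other 3 groups: cry3b and NR1D1 did not overlap with any other group in any of the 6 libraries of either tissue. They share the exposure of the vehicle, unstressed group and the stress of the fluoxetine, stressed group, and the time of day at which each group was sampled is not given in the sources used here.

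A technical explanation for the adult clock pattern is handling of 1 range of library numbers at another time. The median size of the interaction in the 22 hypothalamic clock genes that passed was 1.43 pooled, 1.41 in numbers 1 to 24 and 1.51 in numbers 25 to 48, and in the 21 telencephalic ones 1.1 pooled, 1.05 and 1.24. A shift in 1 range is excluded as the whole of the difference for these genes only. They were picked by the pooled fit over both ranges, which favors genes that move in both. A different time of day at sampling for the vehicle, stressed group remains a candidate explanation. Activator and repressor or output genes of the clock moved in opposite directions, as a shift of phase requires, with interaction medians of -1.43 and 1.47 in the hypothalamus, 2.89 apart, and of -0.87 and 1.1 in the telencephalon, 1.98 apart. A response of the clock to stress that early fluoxetine alters would do the same, so these cannot be told apart without the sampling times.

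A library can also be far from the other 5 of its group. Over 12 measures 17 of 136 groups had such a library by Dixon's test, where chance alone gives about 1 in 20 groups, 6.8 here. In larval heads, fluoxetine, stressed replicate 2 had FOS (ENSDARG00000031683) at 232.3 CPM (others 19.13 to 44.27), egr1 at 254.1 (others 128.8 to 133.2) and NPAS4 (ENSDARG00000055752) at 440.8 (others 41.51 to 95.65). Vehicle, unstressed replicate 6 had FOS at 17.25 CPM (others 3.744 to 7.965) and NPAS4 (ENSDARG00000055752) at 65.36 (others 9.021 to 14.08). Fluoxetine, unstressed replicate 1 had FOS at 5.19 CPM (others 11.85 to 13.06) and NPAS4 (ENSDARG00000055752) at 10.29 (others 36.86 to 48.34), and replicate 6 had POMC at 3.086 (others 0.7704 to 1.393) and SLC6A4 at 15.7 (others 9.167 to 10.91).

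In the hypothalamus POMC stood at 12.91 CPM in vehicle, stressed replicate 1 (others 20.59 to 24.71) and at 46.82 in fluoxetine, stressed replicate 6 (others 24.08 to 29.9). Among fluoxetine, unstressed libraries egr1 stood at 308 CPM in replicate 4 (others 504.4 to 593.6) and SLC6A4 at 2.616 in replicate 2 (others 0.1385 to 0.9967). In the telencephalon egr1 stood at 377.4 CPM in vehicle, stressed replicate 5 (others 420.9 to 441.5). In fluoxetine, stressed libraries d4EGFP stood at 62.61 CPM in replicate 1 (others 124.7 to 143.4) and NR3C1 at 92.56 in replicate 5 (others 109.4 to 118). The mitochondrial share of counts was 14.25% in fluoxetine, unstressed replicate 6 (others 8.71 to 10.09). For these single libraries no explanation was tested.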

How the results depend on the processing

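Leaving out larval vehicle, unstressed replicates 1 to 3, the axis covariate and each range of adult library numbers alone were chosen after the data were seen; the other alternatives were planned. Of 200 alternative values for 34 counts, 110 lay within 1.5 times the value reported and 90 did not. Of 6359 alternative values for named genes 528 no longer passed, 53 newly passed and 11 changed direction. Those 11 passed in the reported or the alternative fit, since a change of direction where neither passed was not counted. The other 5767 stayed on their side of the threshold. Median-of-ratios size factors left every named gene on its side and each count within 1.5 times, with 0.018 as the largest shift of a median fold, but turned the majority for stress with fluoxetine in the telencephalon from 46.7% to 53% higher. Counts of shared genes over genes with a mean log2 CPM of at least 1 also stayed within 1.5 times. These are 15 of the 110, and they reuse the same calls on fewer genes without a new fit, so they test little. Below, counts are genes past the threshold in edgeR unless named otherwise, set against the counts in the report; the cause was not tested except where stated.

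DESeq2 passed more genes: in larval heads 3319 for fluoxetine in unstressed fish, 758 for stress with fluoxetine and 262 in the interaction; in the hypothalamus 716 for fluoxetine in stressed fish and 285 in the interaction; in the telencephalon 2596 and 1308 for fluoxetine in unstressed and stressed fish and 406 in the interaction. Voom with quality weights passed in larval heads 11626, 4435 and 10806 for fluoxetine in unstressed fish, stressed fish and averaged, 11776 and 1910 for stress with vehicle and fluoxetine, and 8623 in the interaction. In the hypothalamus it passed 1494 for fluoxetine in stressed fish, 2048 for stress with fluoxetine and 1987 in the interaction, and in the telencephalon 4542, 1921 and 5821 for fluoxetine in unstressed fish, stressed fish and averaged, 4694 for stress with fluoxetine and 393 in the interaction. Without a filter the larval interaction gave 14 and fluoxetine in the unstressed telencephalon 839, where more genes enter the adjustment by construction.

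With the replicate number as a block, which met the rule for pairing in no pair of groups, larval heads gave 618 for fluoxetine in unstressed fish, 2153 for stress with vehicle and 1 in the interaction, and the telencephalon 3378 and 1363 for fluoxetine in unstressed and stressed fish and 223 in the interaction. The range of library numbers as a term gave 2167 for fluoxetine in the unstressed telencephalon. It raised the other 11 adult counts too, each within 1.5 times. A fit of only the 2 groups compared estimates the spread from those 12 libraries: in larval heads 35 and 2928 for fluoxetine in unstressed and stressed fish and 431 and 1402 for stress with vehicle and fluoxetine; in the telencephalon 444 for fluoxetine in unstressed fish and 3037 and 3752 for stress with vehicle and fluoxetine.

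Without the libraries that stand apart, which in larval heads are all 6 of vehicle, unstressed, 4 of the 6 larval comparisons had no value, fluoxetine in stressed fish gave 2925 and stress with fluoxetine 1419; in the hypothalamus, without vehicle, stressed replicates 1 and 4, the interaction gave 384. The telencephalon had 0 such libraries, so the alternative gave no value there. Without vehicle, unstressed replicates 1 to 3 larval heads gave 758 and 2764 for fluoxetine in unstressed and stressed fish and 542 and 1322 for stress with vehicle and fluoxetine. In that setting RBP2 (ENSDARG00000093774; log2 0.15), CASQ1 (0.59), ACTA1 (ENSDARG00000055618; 0.16) and ACTC1 (ENSDARG00000057911; 0.29) changed direction for fluoxetine in unstressed larval heads, as did CASQ1 (0.29), and2 (ENSDARG00000079302; 0.91), oxct1b (ENSDARG00000054319; 0.38) and AGR2 (ENSDARG00000070480; 0.94) for stress with vehicle; none of these 8 passed.

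The axis covariate gave in larval heads 3438 and 5358 for fluoxetine in stressed fish and averaged, 1300 and 1683 for stress with vehicle and fluoxetine and 118 in the interaction; in the hypothalamus 1185, 687 and 2472 for fluoxetine in unstressed fish, stressed fish and averaged, 2144 for stress with fluoxetine and 172 in the interaction; in the telencephalon 947 and 1119 for fluoxetine in unstressed and stressed fish. It turned ACTA1 (ENSDARG00000055618; log2 0.02) for fluoxetine in unstressed larval heads and and2 (0.16) for stress with vehicle, neither passing.

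Adult libraries numbered 1 to 24 alone, with 3 per group by construction, gave in the hypothalamus 2292 and 180 for fluoxetine in unstressed and stressed fish, 1645 and 349 for stress with vehicle and fluoxetine and 35 in the interaction. In the telencephalon they gave 0, 175 and 131 for fluoxetine in unstressed fish, stressed fish and averaged, 1565 and 609 for stress and 36 in the interaction; beside the 0, edgeR had 2843 genes at an unadjusted p under 0.05 and DESeq2 passed 120. Libraries numbered 25 to 48 gave in the hypothalamus 1, 32 and 20 for fluoxetine in unstressed fish, stressed fish and averaged, 3695 and 88 for stress and 7 in the interaction, and in the telencephalon 5, 49 and 156, 2325 and 674, and 18. Between the ranges the hypothalamic effect of fluoxetine in unstressed fish went from 2292 to 1, the latter with 3320 genes at an unadjusted p under 0.05 and 574 by DESeq2. The gene isg15 (ENSDARG00000086374) averaged over stress states changed direction in numbers 1 to 24 (log2 0.13), not passing. Sums of replicates n and n+3, also 3 per group, gave in the hypothalamus 202 for fluoxetine in stressed fish, 639 for stress with fluoxetine and 62 in the interaction, and in the telencephalon 20, 237 and 906 for fluoxetine in unstressed fish, stressed fish and averaged, 3025 and 1154 for stress and 81 in the interaction.

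Of the 234 list tests that passed camera with its preset, 4 passed with an estimated correlation, which by construction widens the test for lists whose genes move together; on ranks 240 passed and with the replicate block 232. In unstressed larval heads ern1, PLCD3, npvf and cyp2ad3 passed for fluoxetine in every alternative that gave a value. Simulated data had each gene's own mean and dispersion, with genes drawn independently and only genes above a mean log2 CPM of 1 changed. There edgeR recovered 24% of larval genes changed 1.5-fold, 45% in the hypothalamus and 60% in the telencephalon. How far depth sets this was not tested.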

Other observations

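Several choices were made only after results were seen: the lists of liver, cerebellum and photoreceptor genes, the axis covariate, the fits of each range of library numbers alone, the look at which splits called many genes, and the match between adult tissues by number. The other tests were planned. Some stress responses recur in both exposures and were not described above. The pseudokinase gene TRIB3 (ENSDARG00000016200), of the unfolded protein response, rose with stress 2.08-fold in vehicle and 2.1-fold in fluoxetine larval heads, 3.49-fold and 2.79-fold in the hypothalamus, and 2.95-fold and 2.5-fold in the telencephalon (n = 6 libraries per group). CHAC1 (ENSDARG00000070426), on the same list, rose 2.03-fold and 1.82-fold in larval heads. In the telencephalon of fluoxetine fish 13 of 34 genes of that list were higher with stress and 1 lower (14 and 3 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). The adrenergic receptor gene ADRA2B (ENSDARG00000102096) rose 2.14-fold and 1.66-fold in the telencephalon.

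Photoreceptor genes were higher with stress in vehicle larval heads for 22 of 53 (25 adjusted over the list alone; adjusted p = 0.478 with an estimated correlation), among them ARR3 (ENSDARG00000098475), a cone arrestin gene, at 2.14-fold. In the hypothalamus of stressed fluoxetine fish myelin genes were higher for 4 of 26 (6 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), with CLDN11 (ENSDARG00000020031) at 1.89-fold. Between adult tissues, hypothalamic and telencephalic libraries of the same group and number had residuals that correlated with a mean r of 0.27 across genes, which are not independent replicates. In 17 of 24 cases the best match within the group had the library's own number, against 4 by chance; whether both tissues came from the same fish is not given in the sources used here.

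The larval vehicle, unstressed libraries spread widely: their mean log2 CPM over the liver list spanned 4.26, against 2.12, 2.07 and 0.70 in the other larval groups. Thinning all larval libraries to 10.2 M counts left a span of 4.24, 99.5% of it. These values are already scaled by library size, so thinning was a weak test. The totals argue against library size as the cause. Replicates 1 to 3 held 17.8, 18.2 and 19.8 M counts, and replicates 4 to 6 held 16.6, 19.9 and 19.6 M. Trunk tissue left on some dissected heads is a candidate explanation: posterior Hox genes spanned 3.37 in this group, but also 2.94 in fluoxetine, unstressed libraries, 1.26 and 1.76 in the stressed groups, while anterior Hox genes spanned 0.44 to 0.65 in all 4. This test cannot tell, because the span was wider than in any other group but by less than set beforehand. The set holds only 5 genes at low levels. In the vehicle, unstressed group their mean log2 CPM was 0.68 to 1.15 in replicates 1 to 3 and -2.21 to -0.26 in replicates 4 to 6. Yet fluoxetine, unstressed replicate 2 reached 0.93 with a liver mean of 3.77, below the 6.02 to 6.47 of vehicle, unstressed replicates 1 to 3. A difference in the developmental state of the pools was not tested and remains open.

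In the unstressed hypothalamus 53 of 72 ribosomal protein transcripts were lower with fluoxetine (71 adjusted over the list alone), by a median log2 of -0.43 (adjusted p = 0.555 with an estimated correlation). They were lower with stress in vehicle fish too, against the same vehicle, unstressed libraries, so those results are not independent. In the telencephalon the median log2 of these transcripts with fluoxetine was -0.31 (adjusted p = 0.627 with an estimated correlation), and rps20 (log2 -0.38, adjusted p = 0.0833) did not pass. A shift in 1 range of library numbers is excluded as the whole of it: the medians were -0.55 and -0.36 in the hypothalamus, and -0.21 and -0.41 in the telencephalon, in numbers 1 to 24 and 25 to 48. With the main axis of variation within groups as a covariate the telencephalic median was -0.27 (quartiles -0.30 and -0.22), 87% of its size, which excludes that axis as the whole cause there. In the hypothalamus the median was -0.33 (quartiles -0.39 and -0.27), 75.2% of its size, and the count of members lower went from 53 to 0, so that a part played by the axis, which holds 24.9% of the variation within groups and whose nature is not known, cannot be told apart from an effect of early fluoxetine.

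For each count of genes past the threshold, 100 splits of the same libraries into groups of the same sizes were taken, the real one included. In larval heads chance is not excluded for fluoxetine in unstressed fish, where 11 of 100 splits passed at least the real 2191 genes and the highest other passed 6807. Nor is it for stress in vehicle fish, where 8 of 100 passed at least 4303 and the highest other 9857. These high counts point to a structure of the samples: each of the 10 other splits as large in the former and each of the 7 in the latter had vehicle, unstressed replicates 1 to 3 on 1 side, as did 19 and 14 of the 99 other splits in all. In the other larval comparisons 1 of 100 splits, the real one, was as large. These were fluoxetine in stressed fish (1052, highest other 1), averaged (3238, highest other 2170), stress with fluoxetine (473, highest other 2) and the interaction (27, highest other 0). Such counts are rare among splits of these libraries, which does not exclude chance. The interaction splits exchange stress labels within each exposure. They break up the stress effect too, and a split can keep part of it in 1 exposure only. For that reason they cannot test the interaction alone.

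In the hypothalamus few splits were as large as the real one in any of the 6 comparisons, which shows rarity and does not exclude chance. For 5 of them 1 of 100 splits was as large: fluoxetine in unstressed (4478; highest other 4171) and stressed fish (380; 85) and averaged (5022; 7), and stress with vehicle (6762; 4444) and with fluoxetine (1192; 91). For the hypothalamic interaction it was 3 of 100, with 94 genes in the real and 2080 in the highest other split. A split that keeps part of the stress effect in 1 exposure can give such a number, so nothing is concluded from it on the structure of the samples. Splits as large as the real one were rare in the telencephalon as well. There 2 of 100 were as large for fluoxetine in unstressed fish (1435, highest other 1731) and 1 of 100 for fluoxetine in stressed fish (645, 0) and averaged (3489, 1). It was also 1 of 100 for stress with vehicle (4928, 3359) and fluoxetine (2499, 3) and for the interaction (147, 3). Both adult interactions carry the limit given for the larval one, since their splits also exchange stress labels within each exposure. Whether these other large splits followed the ranges of library numbers is not settled. In the 1 telencephalic split the sides differed by 2 of 6 libraries numbered 1 to 24, against at most 4 in any split. In the 2 splits of the hypothalamic interaction they differed by at most 4 of 12, against at most 6 in any split. That measure adds both exposures, so opposite imbalances in them cancel.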
